A study of Arabidopsis thaliana with 3 samples.

How the data were processed

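RNA of 35S:AtIBH1-SRDX and of wild-type Arabidopsis seedlings was compared directly on 3 2-colour Agilent arrays of the 4x44k format, 1 for each of 3 biological replicates per the series' design text. Seedlings grew for 10 days on agar with 1% sucrose at 23 °C under 16 h of light and 8 h of dark, and 1 µg of total RNA was labelled, per the labels' protocols. On arrays 1 and 3 Cy3 held IBH1-SRDX and Cy5 wild type, and on array 2 the dyes were swapped, per the labels. The arrays shared 1 slide and 1 scan, so neither divides them. Whether the replicates were grown, harvested or labelled on different days is not given in the sources used here.

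The deposited scanner files hold spot and local background intensity values (median of pixels) in each channel, written by Agilent Feature Extraction 9.1.3.1, per the file headers and the submitters' processing notes. They also hold that program's log10 ratio of Cy5 over Cy3, background-subtracted and dye-normalized, per the file headers, and flags of 0 or 1 for each spot. The deposited series table holds natural log ratios, with the scale, sign and centring found here from the values, as follows. Among probes well above background in both channels its columns had a slope of 1.00 on the natural log ratio of IBH1-SRDX over wild type from the scanner files (r of 1.00 across probes on each array), less a constant of 0.0929 that is the same on all 3. Its column medians were 0.0012, -0.222 and 0.0033. How dim probes and that constant were set stays unknown.

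Each array had 39102 spots, 1417 of them controls, for 37478 probes. Of these, 26236 carried an Arabidopsis locus, for 25665 loci, 8812 were named by chromosome position and 2430 by other accessions, of which 0 matched the reference. Median local backgrounds lay between 53 and 58 units. Spots well above background made up 60.8% (IBH1-SRDX) and 63.0% (wild type) on array 1, 62.2% and 58.8% on array 2, and 61.4% and 63.5% on array 3. Gene symbols came from the array's loci through the TAIR10.1 gene table, where 19769 of 19875 tested loci were found. No coordinates were used, since the array's build is not given in the sources used here.

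The preparation was fixed before the data were examined, with 2 departures. It named mean signals, but the files read here hold median signals, which were used in their place. Secondly, 4 local backgrounds of Cy3 and 5 of Cy5 on array 1 exceeded 200 units, with a maximum of 65206, and with them normexp added a large constant to every spot of that array. The lowest average log2 intensities (1st percentile) were then 9.66 on array 1 against 5.91 and 6.36 on the other arrays. Local backgrounds that Feature Extraction marked as outliers therefore took the median of the unmarked backgrounds of their array and channel, after which that percentile was 5.88, 5.90 and 5.97. This choice was made after seeing the data. An added alternative keeps these backgrounds as first written, with median signals still in place of mean signals. Background was corrected with normexp (offset 50), log ratios were normalized within arrays by loess with control spots at weight 0, and control spots and spots marked as non-uniform or population outliers were left out (91 to 189 spots per array), while saturated spots would have stayed. Spots of a probe were averaged, probes were kept where a genotype was well above background on all 3 arrays, and the brightest probe stood for a locus. Of 377 tested loci with more than 1 kept probe, 136 were called, and in 15 of these the probes differed in sign.

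Log2 ratios were turned to IBH1-SRDX over wild type and tested against 0 with lmFit and eBayes of limma 3.58.1 in R 4.3.3 (files were read with data.table, version 1.17.8), with Benjamini-Hochberg adjustment over 19875 loci and calls at an adjusted p below 0.05. The fit had 2 residual degrees of freedom per gene and 4.88 from the prior. A sign-flip test of a single gene on 3 arrays cannot go below an exact two-sided p of 0.25, so every call rests on limma's pooled spread. Since 2 of 3 arrays share a dye orientation, 33.3% of a probe's dye bias stays in the mean, and a dye term, which leaves 1 residual degree of freedom, was an alternative. With it, 0 genes had a called dye effect, and the median absolute dye coefficient was 0.086 (log2). The dye contrast sets 1 array against 2 and has little power, so the 0 does not show that dye bias was absent. Calls with the dye term were 4630 higher and 4797 lower. Where a genotype was not well above background on any array, the fold is a lower bound. It sets the mean of the brighter genotype against that of the dimmer, per channel after loess and Aquantile, and is open to dye bias. Each array of the dimmer genotype stands at the higher of its own value and the lowest signal among probes well above background. Where its own values are the higher on every array, the bound equals the fitted fold. The bound makes no allowance for spread between arrays.

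The genes named were chosen by a rule written before the data were examined, apart from those marked as chosen after the values were seen. IBH1 came first, then the 12 largest rises and the 12 largest falls among called loci of 1 sign on all 3 arrays, then up to 4 members with the smallest adjusted p of each gene list. The lists, 23 of them with 386 members written from textbook knowledge and 2 more by the plastid and mitochondrial prefixes of the loci, were fixed at the same time. Symbol and locus matched the reference for 376 members, and 10 were used by locus alone. Lists with at least 5 measured members were tested with limma's camera (preset correlation 0.01, Benjamini-Hochberg over 22 lists). An estimated correlation and fry were used beside it. Loci missing on an array were left out of these tests, though they count among the measured members. With an estimated correlation camera uses the 2 residual degrees of freedom of the fit, so its p can rise even where that correlation is low. Alternatives covered the background correction, the normalization, Feature Extraction's log ratio, the deposited series table, scaling between arrays, a dye term, the filter on dim probes, the probe rule, the variance model, a 2-fold threshold and each replicate left out.

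The procedure was tested on simulated data for this comparison, 3 arrays with dye bias and background in which 19928 loci were fitted. Of 50 genes at each size, it called 14 with a log2 change of 0.5, 48 with 1, 50 with 2 and 50 with 4, with 0 of the wrong sign. It called 6 of 19706 unchanged genes, 0 of 20 unshifted lists, and the list shifted by -0.5, with a mean of -0.48. Noise was drawn for each probe independently and lists were drawn at random. The simulation therefore does not test camera on correlated members, and estimated correlations in the real lists reached 0.735. Most simulated genes were unchanged, whereas 38.4% of tested loci were called in the data, so loess and false calls were not tested in that setting. Median estimated sizes were 0.44, 0.93, 1.87 and 3.78.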

Results

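Whole seedlings of Arabidopsis thaliana (Col-0) that carry 35S:AtIBH1-SRDX were compared with wild-type seedlings 10 days after sowing. IBH1 (AT2G43060) is a helix-loop-helix protein that holds back cell elongation by binding basic helix-loop-helix (bHLH) factors. SRDX is a short repression domain derived from the plant protein SUPERMAN, and the 35S promoter drives expression throughout the plant. The comparison asks which transcripts differ when IBH1 fused to this domain is produced. RNA of each genotype was hybridised together on 3 Agilent 2-colour arrays, 1 per biological replicate pair, with the dyes swapped on 1 array. Between 58.8% and 63.5% of the spots were well above background in each channel, no spot was saturated, and 19875 loci were tested. The number of arrays limits the precision of every value. Values are log2 ratios of IBH1-SRDX over wild type ± SE with n = 3 unless stated. The SE is that of limma, where each gene's variance is drawn toward the variance pooled over genes. It therefore does not measure the spread of a gene's own arrays. For ARD3 the SD of the arrays was 1.73 beside an SE of 0.54, and for CPD 0.04 beside 0.08.

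The probe for IBH1 itself was lower in the RNA labelled IBH1-SRDX, with log2 ratios of -0.88, -0.60 and -0.67 on the 3 arrays (mean -0.71 ± 0.09, adjusted p = 0.00118). Its place in the transcript is not given in the sources used here, so it may lie in a part that the transgene lacks, and it then checks nothing about the labels. Every direction below therefore rests on the labels, and IBH1-SRDX stands for the RNA so labelled. A single probe stood for IBH1, well above background in each channel of the 3 arrays.

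The largest falls were those of GASA6 and EXPA8. GASA6, a gibberellin-regulated small peptide, fell by 3.95 ± 0.34 (adjusted p = 0.000307), and the expansin EXPA8, which loosens cell walls, fell by 3.27 ± 0.22. The signalling peptide gene CLE2 stood at -3.14 ± 0.14, the arabinogalactan peptide gene AGP14 at -3.01 ± 0.08 and the cytochrome P450 gene CYP78A8 at -2.94 ± 0.14. AIF1, an atypical bHLH factor related to IBH1, stood at -2.83 ± 0.13. The methionine sulfoxide reductase gene MSRB6 stood at -2.70 ± 0.12, and TIP2;1, a water channel of the vacuole membrane, at -2.61 ± 0.10. AT1G52190, a transporter of the nitrate transporter family, stood at -3.14 ± 0.12, AT5G03120 at -2.87 ± 0.11 and AT1G12080 at -2.76 ± 0.14. AT1G66100, of the thionin family, was not well above background in IBH1-SRDX on any array and was at least 5.86-fold lower there. Adjusted p for these 12 genes lay between 1.10e-05 and 0.000307.

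The largest rise was that of the SUP probe (AT3G23130, SUPERMAN), at log2 ratios of 8.06, 8.42 and 7.87, a mean of 8.12 ± 0.11 (adjusted p = 7.93e-07). AT3G29970 followed at 5.62 ± 0.13, AT5G10040 at 5.20 ± 0.12 and PR2, the pathogenesis-related glucanase gene listed in the reference as BGL2, at 4.71 ± 0.26. ARD3, an acireductone dioxygenase gene of methionine salvage, rose by 4.47 ± 0.54, with 5.65, 5.28 and 2.49 on the arrays. UGT74E2, which glucosylates the auxin indole-3-butyric acid, rose by 4.13 ± 0.16, BPS3 by 3.93 ± 0.12 and SRO5 by 3.79 ± 0.13. AT1G12805 stood at 4.21 ± 0.09, AT1G65500 at 3.77 ± 0.16 and AT5G10760, an aspartyl protease gene, at 3.71 ± 0.36 (4.82, 3.77 and 2.53 on the arrays). AT1G13470 stood at 3.82 ± 0.36 (4.65, 4.27 and 2.53 on the arrays), and its wild-type signal was well above background on 1 of the 3 arrays. Without replicate 3 the ratios were 5.47 for ARD3, 4.46 for AT1G13470 and 4.29 for AT5G10760, and without replicate 1 that of ARD3 was 3.89. Adjusted p for these 12 genes lay between 7.93e-07 and 0.00111.

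**Figure D1:**
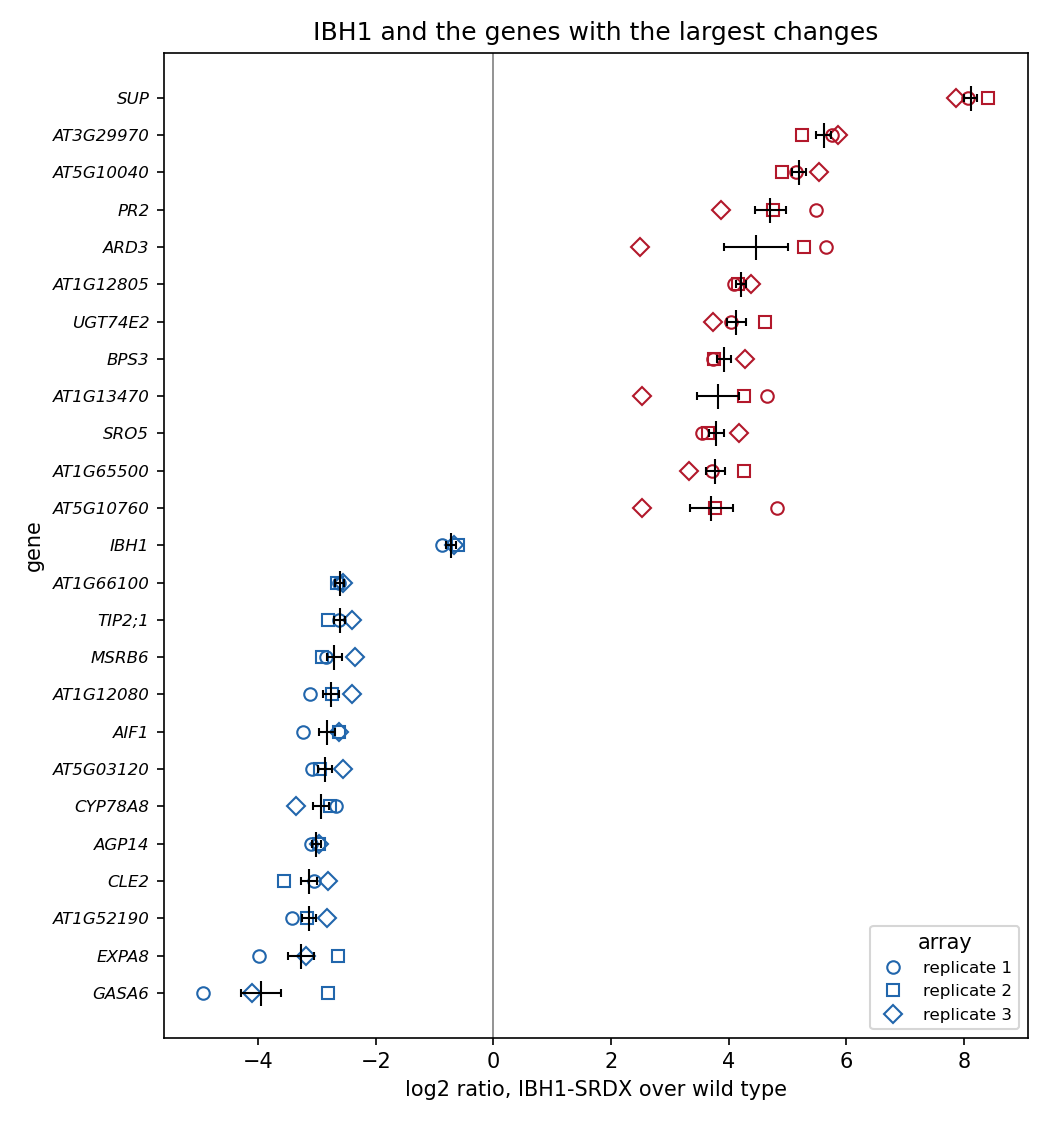
Log2 ratio of IBH1-SRDX over wild type (x axis) of IBH1 and of the 12 genes with the largest rise and the 12 with the largest fall (y axis). Open symbols are the 3 arrays (red where the gene was called higher, blue where lower). Black ticks with bars are the mean ± limma's SE, which uses variance pooled over genes. SUP lies between 7.87 and 8.42 on all arrays and IBH1 between -0.88 and -0.60. AT1G66100 is drawn at its fitted value although its IBH1-SRDX signal was not well above background.

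Across all loci, 3687 transcripts were higher and 3949 lower in IBH1-SRDX at an adjusted p below 0.05 in limma, which is 18.6% and 19.9% of those tested. Of these, 614 were at least 2-fold higher and 424 at least 2-fold lower. Of the 7636 called transcripts, 7551 were measured on all 3 arrays, and 7543 of those had 1 sign on all 3. Log ratios of the arrays correlated across genes, which are not independent replicates, with r of 0.859 (replicates 1 and 2), 0.884 (1 and 3) and 0.808 (2 and 3). The counts of 3687 and 3949 rest on the replacement of outlier local backgrounds, a choice made after seeing the data. With those backgrounds kept, as first written, the counts were 1143 higher and 1919 lower. They were 591 and 674 with median centring in place of loess, and 2319 and 2487 without replicate 1. At least 2-fold higher and lower were 937 and 803 with the Feature Extraction log ratio, 954 and 786 with the deposited series table, and 312 and 289 with outlier backgrounds kept. With median centring the balance turned, at 529 and 577.

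Auxin-responsive SAUR genes, whose products promote cell expansion, were lower. All 15 measured members fell in IBH1-SRDX (15 when adjusted over the list alone), with a median log2 ratio of -1.77 and 12 at least 2-fold lower. SAUR64 stood at -2.52 ± 0.11, SAUR63 at -2.13 ± 0.09, SAUR19 at -2.13 ± 0.11 and SAUR65 at -1.62 ± 0.09. Probes of SAUR19 to SAUR24 may cross-hybridise, so members of that cluster are uncertain one by one. SAUR63, SAUR64 and SAUR65 come from another run of neighbouring loci, and shared signal among their probes was not checked. The Aux/IAA and GH3 early auxin genes had 10 lower, 2 higher and 7 not called of 19 (11 lower and 2 higher when adjusted over the list alone). IAA3 stood at -2.15 ± 0.10, IAA5 at -1.85 ± 0.10, IAA19 at -1.83 ± 0.08 and IAA6 at -1.61 ± 0.08, the last well above background in IBH1-SRDX on 2 of 3 arrays. Camera with a preset correlation gave an adjusted p of 4.03e-11 for the SAUR genes and 0.003 for the early auxin genes, against adjusted p = 0.316 and adjusted p = 0.424 with an estimated correlation.

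Genes of cell wall loosening and of water uptake were mostly lower. Of 22 expansins, 15 were lower, 1 higher and 6 not called (16 lower and 1 higher when adjusted over the list alone), with EXPA11 at -2.16 ± 0.09, EXPA3 at -2.06 ± 0.12, EXPB1 at -1.90 ± 0.08 and EXLA2 at -1.20 ± 0.08. Of 23 xyloglucan endotransglucosylase/hydrolases, which cut and rejoin xyloglucan, 16 were lower, 3 higher and 4 not called, the same counts when adjusted over the list alone. XTH4 stood at -1.90 ± 0.10, XTH20 at -1.82 ± 0.11, XTH6 at -1.73 ± 0.10 and XTH7 at -1.61 ± 0.10, and close XTH pairs may share signal. Of 18 aquaporins, 15 were lower, 0 higher and 3 not called, also when adjusted over the list alone, with a median of -1.09. TIP2;2 stood at -1.87 ± 0.11, PIP2;7 at -1.55 ± 0.10 and TIP1;1 at -1.45 ± 0.08. Camera gave an adjusted p of 3.28e-07 for the expansins, 0.000226 for the xyloglucan enzymes and 9.79e-09 for the aquaporins, each at adjusted p = 0.316 with an estimated correlation. Primary wall cellulose synthesis was not called by camera (adjusted p = 0.112), with 2 of 9 members lower and 7 not called, also when adjusted over the list alone, namely CESA3 at -0.44 ± 0.08 and CSI1 at -0.40 ± 0.08. That list was called with a dye term (adjusted p = 0.046, with 0.046 to 0.355 over the settings of the preparation and fit).

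The helix-loop-helix and bHLH factors of cell elongation, the network to which IBH1 belongs, had 20 of 32 members lower, 6 higher and 6 not called (21 lower and 6 higher when adjusted over the list alone). The list was called by camera (adjusted p = 7.53e-05, and adjusted p = 0.316 with an estimated correlation). Beside AIF1, the smallest adjusted p belonged to IBL1, an IBH1-like gene, at -2.50 ± 0.08, UPB1 at -2.40 ± 0.11 and PAR1, a helix-loop-helix factor of shade avoidance, at -2.11 ± 0.12. Among the 6 higher members PRE4 stood at 1.09 ± 0.10 and BIM3 at 0.77 ± 0.08, both named after their values were seen. The list holds factors that promote elongation and factors that hold it back, so its direction stands for neither kind.

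Brassinosteroid and gibberellin genes were lower in part. Of 12 genes of synthesis and inactivation, 6 were lower, 1 higher and 5 not called (7 lower and 1 higher when adjusted over the list alone), with BR6OX2 at -1.28 ± 0.09 and CPD, a steroid hydroxylase gene, at -1.06 ± 0.08. BR6OX1 stood at -0.84 ± 0.08, its IBH1-SRDX signal well above background on 1 of 3 arrays, and BAS1, which inactivates the hormone, at -0.52 ± 0.09. Of 9 signalling genes, 5 were lower and 4 not called (5 lower and 1 higher when adjusted over the list alone), among them BRS1 at -0.91 ± 0.09 and the receptor gene BRI1 at -0.55 ± 0.09. The gibberellin list had 9 lower, 3 higher and 13 not called of 25, the same when adjusted over the list alone, with GASA1 at -1.28 ± 0.19, the synthesis gene GA20OX1 at -0.74 ± 0.09 and the DELLA gene GAI at -0.67 ± 0.08. Adjusted p by camera was 0.0147, 0.0435 and 0.0435 for these 3 lists, against adjusted p = 0.316, adjusted p = 0.316 and adjusted p = 0.403 with an estimated correlation. Without replicate 1 the calls of the signalling list (adjusted p = 0.0657) and of the gibberellin list (adjusted p = 0.0807) ended, as did that of the signalling list without replicate 2 (adjusted p = 0.0517); over all settings of the preparation and fit adjusted p ran from 0.0313 to 0.105 for signalling and from 0.00487 to 0.0807 for gibberellin.

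Transcripts of the salicylate and immune response were higher, the only list that camera called in that direction. Of its 16 members 15 were higher, 0 lower and 1 not called, also when adjusted over the list alone, with a median of 1.65 and 14 at least 2-fold higher. Beside PR2, the transcription factor gene WRKY53 stood at 2.13 ± 0.15, WRKY40 at 1.55 ± 0.17 and ICS1, which makes the precursor of salicylate, at 1.28 ± 0.11. The list's median was 2.13, 2.04 and 1.00 on arrays 1, 2 and 3. Camera's adjusted p was 7.54e-08, against adjusted p = 0.343 with an estimated correlation.

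Nuclear genes of photosynthesis were lower in 15 of 25 cases, higher in 3 and not called in 7 (17 lower and 4 higher when adjusted over the list alone). LHCA2, of the antenna of photosystem I, stood at -0.85 ± 0.08, and the Rubisco small subunit genes RBCS3B and RBCS1B at -0.89 ± 0.08 and -0.86 ± 0.08, with shared signal possible between them. LHCB1.1 went the other way at 2.06 ± 0.13, and cross-hybridisation within the LHCB1 genes leaves it uncertain. Cell cycle genes had 12 lower, 3 higher and 5 not called of 20, also when adjusted over the list alone, with the inhibitor gene KRP2 at -0.77 ± 0.10, CYCB1;2 at -0.65 ± 0.09 and CYCB2;2 at -0.58 ± 0.08. Of 7 flowering-time genes 4 were lower and 3 not called, also when adjusted over the list alone, with SPL3 at -1.17 ± 0.08 and FLC, a repressor of flowering, at -0.88 ± 0.10. Camera gave adjusted p of 0.000425, 0.0033 and 0.00489 for these 3 lists, each at adjusted p = 0.316 with an estimated correlation.

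Whole seedlings mix organs, and 2 lists of tissue markers were lower. Of 17 xylem and secondary wall markers 14 were lower and 3 not called, also when adjusted over the list alone, with the laccase gene LAC17 at -0.86 ± 0.09 and FLA11 at -0.89 ± 0.08. Of 13 root tissue markers 7 were lower and 6 not called (8 lower when adjusted over the list alone). The Casparian strip gene CASP1 stood at -1.06 ± 0.10 and the nitrate transporter gene NRT2.1 at -1.50 ± 0.20. CASP5 was not well above background in IBH1-SRDX and was 2.24-fold lower there by the fit. Its bound had the same value and was 2.18-fold without replicate 1. Camera's adjusted p was 1.49e-06 for xylem and 0.0033 for root tissue, each at adjusted p = 0.316 with an estimated correlation. Root hair markers were not called by camera (adjusted p = 0.244), with 3 of 9 higher and 6 not called, also when adjusted over the list alone, among them RSL4 at 0.60 ± 0.08. Stomatal lineage and trichome markers were not called by camera either (adjusted p = 0.527), though fry called them higher (adjusted p = 0.025). The list's mean was only 0.04 and its median 0.07, 0.07 and 0.09 on arrays 1, 2 and 3. SPCH was higher at 0.61 ± 0.08 and GL1 lower at -0.60 ± 0.13, with 8 of 10 not called, also when adjusted over the list alone.

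Cold, drought and abscisic acid genes were not called as a list by camera (adjusted p = 0.632), though fry called them lower (adjusted p = 0.025). Of 17, 5 were higher, 6 lower and 6 not called (6 higher and 6 lower when adjusted over the list alone). The list's mean was -0.02 and its median 0.09, 0.02 and -0.12 on arrays 1, 2 and 3, so it had no clear direction. COR15A, a cold-induced chloroplast protein gene, stood at -2.54 ± 0.09 and COR15B at -1.41 ± 0.09, while the alcohol dehydrogenase gene ADH1 stood at 3.04 ± 0.15. Jasmonate and ethylene genes (camera, adjusted p = 0.238) had 6 higher, 4 lower and 3 not called of 13 (8 higher and 4 lower when adjusted over the list alone), with VSP2 at -1.21 ± 0.10 and the ethylene response factor gene ERF1 at 1.26 ± 0.16. Flavonoid genes (camera, adjusted p = 0.0684) had 6 higher, 1 lower and 6 not called of 13 (7 higher and 1 lower when adjusted over the list alone), with MYB111, a flavonol regulator, at 1.11 ± 0.13 and MYBL2, a repressor of anthocyanin synthesis, at -1.79 ± 0.09. Of 10 clock genes PRR5 was higher at 1.24 ± 0.13 and TOC1 at 0.35 ± 0.08, with 8 not called, also when adjusted over the list alone (camera, adjusted p = 0.112). The clock list was called without replicate 1 (adjusted p = 0.0209, lowest to highest over the settings 0.0209 to 0.266). The flavonoid list was called under 6 of 15 settings of the preparation and fit (adjusted p from 0.0181 to 0.393 over all), namely with no filter on dim probes, outlier backgrounds kept, the Feature Extraction log ratio, both genotypes above background, the deposited series table and without replicate 2, and also by fry (adjusted p = 0.0446). Seed storage and maturation, plastid and mitochondrial genes had 3, 1 and 3 measured members and were not tested, with 1 higher (CRU1, at least 3.46-fold, 2.14-fold without replicate 1, not well above background in wild type), 1 lower (ATCG01000 at -0.38 ± 0.09) and 0 called, also when adjusted over each list alone.

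**Figure D2:**
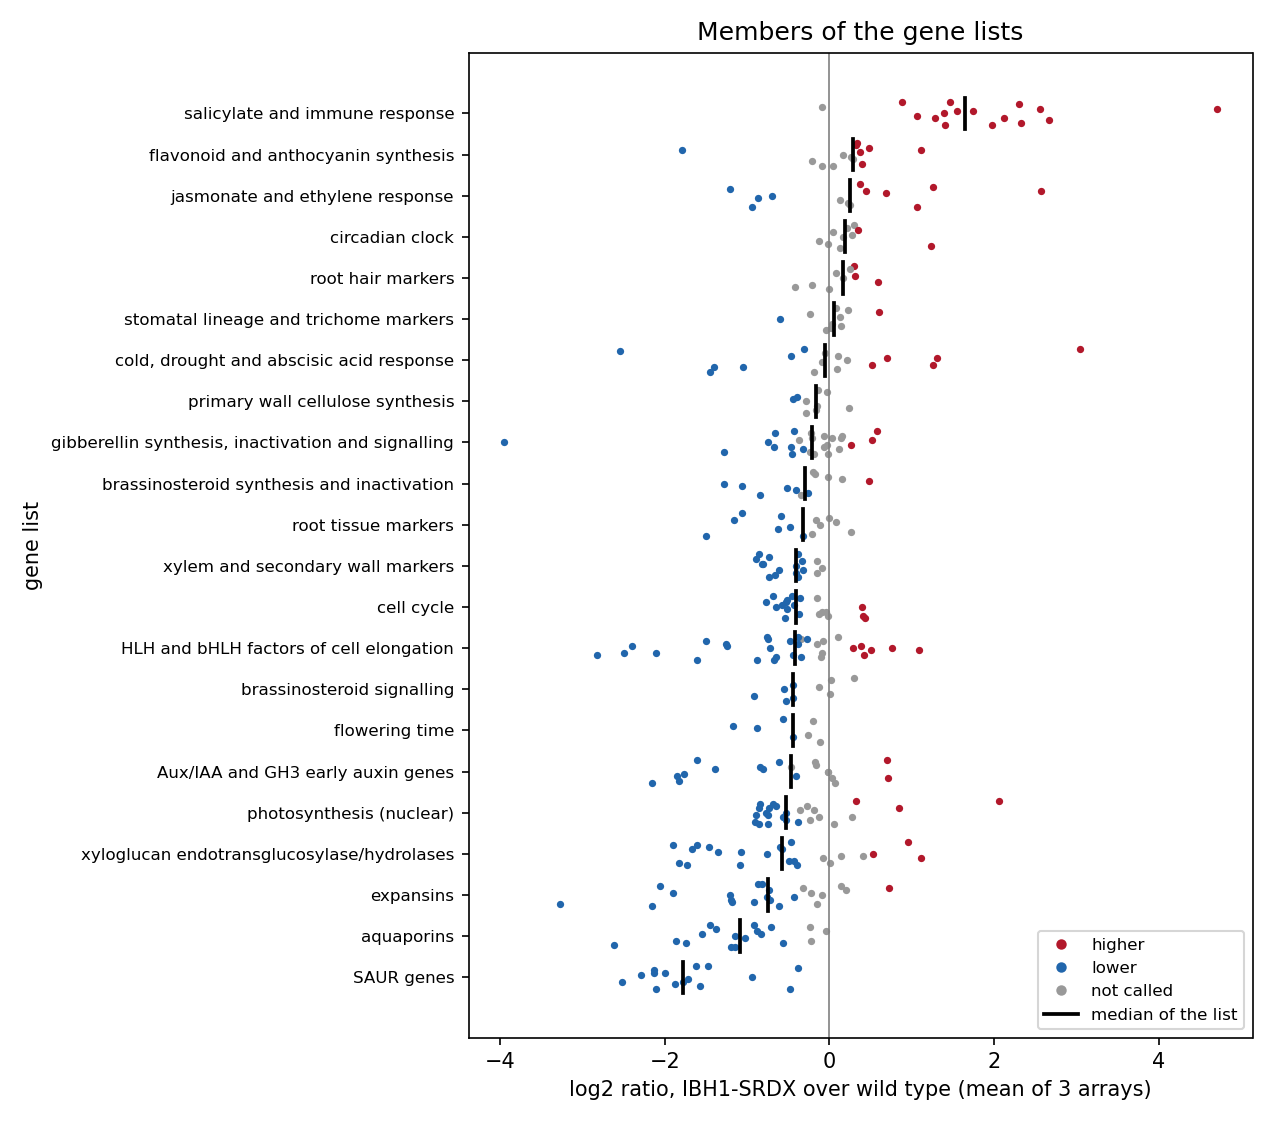
Log2 ratio of IBH1-SRDX over wild type (x axis, mean of 3 arrays, or of 2 for TIP1;2, IAA17, RBCS1A, LHCB4.2 and ELF4) of each measured member of the 22 tested gene lists (y axis). Dots are genes (red where called higher, blue where called lower, grey where not called), drawn at fitted values also where a signal was not well above background, and black bars are list medians, from -1.77 for SAUR genes to 1.65 for the salicylate and immune response.

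In all, 15 of the 22 tested lists were called by camera, 14 lower and 1 higher. None was called with an estimated correlation, where 2 lists had an unadjusted p below 0.05. That setting has 2 residual degrees of freedom and little power. For photosynthesis camera's unadjusted p went from 0.000155 to 0.0528 at an estimated correlation of -0.0016, below the preset 0.01. The lost calls therefore do not show whether correlated members account for the lists. Fry, which asks whether a list's genes move on balance one way without comparing them with other genes, called 18. Among the genes named above, median centring ended the calls of IBH1, BRI1, BAS1, BR6OX1, CESA3, CSI1, GA20OX1, GAI, KRP2, CYCB1;2, CYCB2;2, RSL4, SPCH, GL1, TOC1 and ATCG01000. Their directions stayed, with larger ratios for the lower ones (BRI1 at -0.66, KRP2 at -0.87) and smaller ratios for the higher ones (RSL4 at 0.49). With outlier backgrounds kept the calls of BAS1, BR6OX1, CASP5, ERF1, FLC, GA20OX1, GL1, IAA6, RSL4, SPCH and TOC1 ended, without replicate 1 those of CSI1 and ATCG01000, without replicate 3 those of TOC1 and ATCG01000, and with a trended, robust variance that of CRU1.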

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

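Signal outside the tested loci was found on probes that the comparison did not use. Probes named by chromosome position were well above background in a genotype on all 3 arrays in 1230 cases, and probes named by expressed sequences or other accessions in 848 cases. In a separate fit of these probes with limma, chosen after the data were seen, 146 of the 1230 were higher and 114 lower in IBH1-SRDX at an adjusted p below 0.05, and 76 of the 848 were higher and 93 lower. Of the 1230 probes, 168 passed the background limit on all arrays in IBH1-SRDX but not in wild type, and 83 in wild type but not in IBH1-SRDX. Among the 848 these counts were 83 and 66. These probes are unnamed here, and no explanation was tested for them.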

How the results depend on the processing

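The replacement of outlier local backgrounds in the main preparation was chosen after seeing the data. The alternative that keeps them follows the preparation as first written, apart from the median signals, and was added at that point. All other alternatives were planned. The count of genes higher in IBH1-SRDX (3687) and of genes lower (3949) moved to 591 and 674 with median centring and no loess, to 1143 and 1919 with outlier local backgrounds kept, and to 614 and 424 at 2-fold or more. With backgrounds kept, 37.3% of the calls were higher, against 48.3%, and all 3062 calls were among the 7636. The constant that normexp added on array 1 was then larger, and whether it accounts for these changes was not tested. With median centring 1261 of the 7636 calls remained, 7635 kept their sign, and the cause was not tested. Leaving out a replicate gave 2319 to 3903 higher and 2487 to 4335 lower genes, the lowest without replicate 1. The other alternatives gave 3535 to 4630 higher and 3715 to 4797 lower genes. The IBH1 transcript (-0.71) kept its direction throughout, from -0.83 to -0.53. Its call was lost with median centring (-0.82, adjusted p = 0.119), where the cause was not tested, and over the other alternatives its adjusted p lay between 3.19e-05 and 0.0224. Without a replicate it lay between -0.77 and -0.63. Gene lists past the threshold numbered 15, and 14 to 16 under the other settings of the preparation or fit, replicates left out included (14 to 15), 18 with fry and 0 with an estimated correlation. The lists of brassinosteroid signalling and of gibberellin were each called under 10 of 15 settings of the preparation or fit. The 12 largest rises and 12 largest falls kept their call and sign in all 358 values under alternatives. Among 115 genes followed, 1646 of 1716 values stayed on their side of the threshold, and 1 turned. That was EM6, a seed maturation gene at 0.04 and not called, which was -0.25 without replicate 2 and 0.21 without replicate 3. Signal over background limits loci that are dim in a genotype: 398 tested loci passed the background limit on all arrays in IBH1-SRDX alone and 256 in wild type alone.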

Other observations

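The tests of the low-oxygen list, the floral genes, a reversed array, what the probes read, a single replicate and handling were chosen only after the result was seen. Transcripts that low oxygen induces stood high in the RNA labelled IBH1-SRDX. The list of 51 such genes was written from textbook knowledge after the largest rises had been seen, so its test is not independent of them. Of 50 measured members 47 were higher, 1 lower and 2 not called, with a median log2 ratio of 1.98. Without the 30 genes with the largest rise of all, 38 of the remaining 41 were higher and 1 lower, with a median of 1.58. Camera on those measured on all 3 arrays gave an unadjusted p of 4.26e-19 with the preset correlation. With an estimated correlation camera gave an unadjusted p of 0.157. Named after their values were seen, ERF71, a factor of the hypoxia response also known as HRE2, stood at 3.14, CML38 at 3.21, the haemoglobin gene HB1 at 2.44 and the pyruvate decarboxylase gene PDC2, measured on 2 arrays, at 1.47 (n = 2). ADH1 is the 1 member that also stands in a list fixed beforehand. AT3G29970, AT5G10040 and SRO5, among the 12 largest rises, belong to the list.

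Floral genes were also looked at after the data were seen, since SUP is a floral gene. SEP3 stood at 2.05 ± 0.19 (limma, adjusted p = 0.00041). AP3 was higher (limma, adjusted p = 0.00198) but not well above background in wild type, at least 1.72-fold, or 1.57-fold without replicate 3. PI at 0.18 ± 0.14 (adjusted p = 0.347) and LFY (adjusted p = 0.094, not well above background in IBH1-SRDX) were not called, so 2 of the 4 measured were higher.

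SUP was far brighter and IBH1 dimmer in the RNA labelled IBH1-SRDX on all 3 arrays. Reversed dye labels on 1 array would turn its ratios against the others, and the lowest correlation across genes between arrays was 0.808. Dye bias of these probes is argued against by the fit with a dye term, where the smaller of their effects was 95.9% of that without the term. What stays open is the hypothesis that the SUP probe, at a log2 ratio of 8.12, may read the SRDX part of the transgene, which derives from SUPERMAN, while the IBH1 probe reads a part that the transgene lacks. Probe sequences were not used here, so this and a change of the native SUP and IBH1 transcripts cannot be told apart.

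For the rise of low-oxygen genes, dye bias is argued against by a list median with a dye term at 99.0% of that without one. A single replicate as the source is argued against by array medians from 1.77 to 2.31. Handling or oxygen at harvest that differed between the genotypes in the same way each time could give the same values, and the design cannot tell it from the genotype. A response to the transgene stays open as a hypothesis.

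Immune genes rose less on array 3, with 14 of 16 below both other arrays. Compressed ratios on array 3 as a whole would give a low slope of array 3 on the mean of arrays 1 and 2. That slope was 0.870 across 7536 other called genes, against a ratio of 0.478 for the immune medians. These genes were called from all 3 arrays, which favours genes on which array 3 follows the others. The slope may therefore stand too high and does not settle this explanation. Higher immune transcripts in the wild type of replicate 3 alone would put the whole fall from array 1 to array 3 in the wild-type channel. There stood 1.92% of it (bootstrap 95% interval over genes -14.9% to 11.7%), which argues against the whole fall standing there. The interval takes the 16 genes as independent, although their estimated correlation was 0.735. It does not measure spread between replicates. That share rests on medians of the changes per gene, -0.91 in the IBH1-SRDX channel and 0.02 in the wild-type channel (log2). Taken from the median levels, which changed by -0.36 and 0.10, it was 22.3% (interval -87.0% to 52.7%), a measure added after the result was seen, so a part in the wild type stays open, as does a different immune state of the IBH1-SRDX plants of replicate 3.

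Chance was weighed by turning the sign of single arrays. The 3 arrays allow 4 assignments of signs, too few for a share under 0.05. The real one called 7636 genes, 1 of the 4 reached that count, and the highest of the others was 0. With correlations between arrays of 0.808 to 0.884, turning 1 array cancels shared ratios and widens their spread. The 0 is therefore no count of false calls, and no conclusion on chance was drawn.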
